A study of Homo sapiens with 16 samples.

How the data were processed

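The series holds 16 dual-colour Agilent whole human genome arrays, 4 each of hESC, EB, hESC-EC and HUVEC. Per the labels, sample RNA was labelled with Cy5 and a pooled reference with Cy3 on every array, with no dye swap, so dye effects of single genes cancel only in differences between groups. The reference pooled RNA from stem cells, embryoid bodies, stem cell-derived cardiac and endothelial cells, heart tissue and HUVEC. The arrays were scanned and read with Agilent Feature Extraction 9.5.1. Per the file headers, the scanner files give the mean foreground and median background intensity of each spot on a linear scale, with no normalization. Per the file headers, the files also give the log10 ratio of red over green after Agilent's background subtraction and dye normalization. The deposited value table holds log2 ratios of sample over reference. They matched the log10 ratios of the same array turned to log2 with slopes of 0.999 to 1.00 and r of at least 0.961, and 7.07% to 13.0% of probes per array differed by over 0.02, all of them probes with a log ratio of exactly 0 in the scanner files. How the authors made the value table after Feature Extraction is not stated. Flags per spot (0 or 1) were used as the file headers name them.

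Each array had 45015 spots, of which 43376 were not controls and covered 41000 probes. Intensities were background corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 with R 4.3.3 and the data.table package, version 1.17.8. Spots with a non-uniform or outlying feature or a non-uniform local background in either channel (0.307% to 1.25% of spots) got weight 0 and were left out of all values. Spots with a non-uniform local background (0.0115% to 0.173%) took the array's median background, because on 1 HUVEC array 6 such spots with backgrounds of up to 31783 in Cy5 distorted the normexp fit. That step was chosen after seeing the data, and the fit with all spots is an added alternative. No normalization between arrays was applied. A probe was kept when its Cy5 signal was well above background on at least 3 of the 4 arrays of at least 1 group and it had at least 3 usable arrays in every group, which left 33597 probes. Each gene took its probe with the highest mean intensity, and 6537 of the 24935 genes tested had more than 1 probe. Probes were named from a table of RefSeq accessions and symbols (27664 probes, 67.5%), and the others kept the file's name. The genes XIST and TSIX and genes on the Y chromosome were removed before testing, as part of 133 probes left out.

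All 16 arrays were fitted together in limma with group as the only term, and the 6 differences between groups were tested with its moderated test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with at least a 2-fold difference. Before the data were examined, 22 gene lists with 613 entries (607 on the array) were fixed from textbook knowledge: endothelial, arterial and Notch, venous and lymphatic, angiogenic factors and receptors, endothelial activation, pluripotency, primitive streak and mesoderm, endoderm and fetal liver, neuroectoderm and neuron, cardiac muscle, smooth muscle and pericyte, fibroblast and interstitial matrix, basement membrane, epithelial, blood cell, cell cycle, hypoxia response, immediate early and heat shock, interferon response, antigen processing, HOX and imprinted genes. The sort markers PECAM1 and CDH5 are in no list. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Counts per list were made over all genes tested and adjusted over the list alone.

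The rule for genes named was fixed before the data were examined. It takes the sort markers, the 6 largest positive and 6 largest negative differences in hESC-EC against EB, hESC-EC against HUVEC and EB against hESC, and the 3 and 3 largest in the other comparisons. These are taken among called genes whose groups do not overlap, that are bright on all 4 arrays of the brighter group and that have a current symbol. It adds up to 3 called members of each list that passed or had a large share of members called. Where the lower group was never well above background, the difference is given as a lower bound against the dimmest signals still well above background on the arrays of that group. The number of arrays, 4 per group, limits the precision of every value.

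The likeness of hESC-EC to HUVEC and EB was compared with an exact permutation test over 70 assignments of arrays. The overlap of the hESC-EC and HUVEC differences from EB was compared with 100 simulated data sets of unchanged groups that share their controls, and recomputed with the EB arrays divided. The scanner files showed 6 slides and 2 scan sessions. HUVEC arrays were all in session 1, and EB replicate 4, hESC-EC replicate 1 and hESC replicate 2 were scanned in the session other than the rest of their group. Each comparison was refitted with slide and session as blocks and within each session or slide that held both groups. The fit was tested on simulated data with known changes, where nearly all 4-fold and 8-fold changes were called, fewer 2-fold changes passed the 2-fold minimum, and hardly any unchanged gene was called.

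The alternatives tried were no background subtraction, Agilent's log ratios, the value table, median centring, quantile normalization of intensities and scaling between arrays, no filter or a stricter filter, the mean of all probes, no minimum fold, a stricter adjusted p of 0.01, only the groups compared, trend and robust settings, array weights, the replicate number as a block, and leaving out each array. All spots in the background fit, the fits within sessions and slides and the fit without EB replicate 4 and hESC replicate 2 were added after seeing the data. The hESC arrays had, per the labels, been part of an earlier series, and their RNA was extracted in another way (Trizol before the columns), so group and extraction cannot be told apart for hESC. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.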

Results

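RNA from 4 kinds of human cells was measured on 16 dual-colour whole-genome oligonucleotide arrays, 4 arrays per group. The groups were undifferentiated human embryonic stem cells (hESC), day 12 embryoid bodies (EB), endothelial cells derived from human embryonic stem cells (hESC-EC) and human umbilical vein endothelial cells (HUVEC). Embryoid bodies are floating aggregates in which stem cells differentiate into many cell types, and those used here came from the H9 line. The hESC-EC were sorted from H9 embryoid bodies on the surface proteins CD31 and CD144 and then cultured further. The genes of those proteins, PECAM1 and CDH5, are therefore the markers of the sort. Each sample carried the dye Cy5 and was hybridised against 1 pooled reference in Cy3, so every value is a log2 ratio of sample to reference. The share of spots with a Cy5 signal well above background was 66.9% to 69.7% on the HUVEC arrays, 69.2% to 82.5% on EB, 74.4% to 78.7% on hESC-EC and 75.4% to 82.2% on hESC. The median Cy5 signal per array lay between 131 and 418. After filtering, 24935 genes were tested. Values of genes are given as the mean log2 ratio ± SD over the 4 arrays of a group, the group named first coming first, and probe positions refer to build NCBI36. A value given as a difference is on the log2 scale, the group named first minus the other. The p-values measure only the spread between these arrays. The labels do not say whether the 4 HUVEC arrays are separate donors, cultures or aliquots of RNA, and their median SD over genes was the smallest (0.0865, against 0.120 to 0.180 in the other groups). Every SD and p-value with HUVEC is limited to whatever those arrays represent. The titles of the EB and hESC-EC arrays give only a replicate number. Whether those are separate differentiations or sorts was not established here, so their values carry the same limit. The labels also do not name the line of the hESC arrays, which came from an earlier series with another RNA extraction, so in each comparison with hESC these cannot be separated from cell type.

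The comparison of hESC-EC with EB asked what differed between the embryoid bodies and the endothelial cells taken from such bodies. Many genes of liver, matrix and epithelium were lower in the sorted and cultured cells. TTR, which encodes the plasma carrier transthyretin, stood at -4.31 ± 0.12 against 4.27 ± 0.49, a 384-fold difference (adjusted p = 3.8e-10, chromosome 18, 27432718 to 27432777). DCN, which encodes the matrix proteoglycan decorin, stood at -3.92 ± 0.19 against 4.44 ± 0.22 (adjusted p = 1.8e-14, 3 EB arrays, chromosome 12, 90063965 to 90064024). Among the genes higher in hESC-EC was CLEC14A, an endothelial membrane lectin, at 0.62 ± 0.11 against -3.26 ± 0.45 (adjusted p = 2.6e-09). Of the sort markers, PECAM1 (chromosome 17, 59754276 to 59754335) was higher in hESC-EC at -0.75 ± 0.10 against -2.18 ± 0.24 (adjusted p = 3.3e-06). CDH5 (chromosome 16, 64994895 to 64994954) differed by 0.83 (-0.70 ± 0.16 against -1.53 ± 0.26, adjusted p = 2.6e-05), short of the 2-fold minimum, and passed it at 1.31 with median centring and at 1.20 with the scanner software's own log ratios.

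The 41 measured endothelial genes went both ways in hESC-EC against EB, 13 higher, 8 lower and 20 not called (camera adjusted p = 0.189, which became 0.0355 with median centring). LMO2, a cofactor in blood and endothelial transcription complexes, differed by -3.56, and KDR, the main receptor of vascular endothelial growth factor, by -3.46. The arterial and Notch list had 2 higher, 8 lower and 12 not called (camera adjusted p = 0.0146, adjusted p = 0.531 with an estimated correlation). In its mean hESC-EC replicate 1 lay apart from the others of its group (-1.14 against -0.98). Its members with the largest differences were the chemokine receptor CXCR4 (-4.22), the gap junction gene GJA4 (-2.87) and the Notch target HEYL (-2.71). Of the 39 angiogenic factors and receptors, 11 were higher, 4 lower and 24 not called (camera adjusted p = 0.0640). CCN2, a matrix-associated growth regulator, rose 26.0-fold and THBS1, the matrix protein thrombospondin 1, 18.5-fold. The endothelial activation list had 4 higher, 3 lower and 14 not called (camera adjusted p = 0.189). Among them, TNFAIP3, a brake on NF-kB signalling, differed by -3.10. The antigen processing list had 5 higher, 0 lower and 13 not called (camera adjusted p = 7.2e-03, adjusted p = 0.437 with an estimated correlation), including the immunoproteasome subunits PSMB9 (3.88) and PSMB8 (2.80) and the peptide transporter TAP1 (2.33). Other genes much higher in hESC-EC were MLPH, a melanosome transport adaptor (34.6-fold), PTX3, a secreted pattern recognition protein (34.0-fold), FHL2, a LIM domain cofactor (32.4-fold), and HCLS1, an actin-binding adaptor known from blood cells (25.8-fold).

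In 8 of the lists for other lineages and cell states, more genes were called lower than higher in hESC-EC against EB and the list passed. The endoderm and fetal liver list had 0 higher, 23 lower and 7 not called (camera adjusted p = 1.0e-08, adjusted p = 0.437 with an estimated correlation). Among them, the plasma protein gene AHSG stood at -4.28 ± 0.24 against 3.96 ± 0.69 and AFP at -4.03 ± 0.23 against 3.88 ± 0.66. The epithelial list had 0 higher, 14 lower and 11 not called (camera adjusted p = 5.7e-06, adjusted p = 0.437 with an estimated correlation). Among them, the adhesion gene CDH1 differed by -6.70 and EPCAM by -6.17. The fibroblast and interstitial matrix list had 3 higher, 17 lower and 6 not called (camera adjusted p = 5.6e-03, adjusted p = 0.757 with an estimated correlation). Among them, LUM, a collagen-binding proteoglycan, differed by -7.76 and the collagen gene COL3A1 by -5.68. The hypoxia response list had 1 higher, 13 lower and 10 not called (camera adjusted p = 7.1e-04, adjusted p = 0.531 with an estimated correlation). Among them, SLC2A1, a glucose transporter, differed by -4.15 and NDRG1 by -2.81. EB replicate 4 lay apart from the other EB arrays in its mean of the endoderm and fetal liver list (1.31 against 1.96), the fibroblast list (0.95 against 1.31) and the hypoxia response list (1.14 against 0.62). The pluripotency list had 1 higher, 16 lower and 13 not called (camera adjusted p = 0.0177, adjusted p = 0.792 with an estimated correlation, lost at 0.0585 with all spots in the background fit). hESC-EC replicate 1 lay apart in the mean of this list (-3.16 against -2.75). Among its members, MYCN differed by -4.64 and SOX2 by -3.76. The primitive streak and mesoderm list had 0 higher, 9 lower and 12 not called (camera adjusted p = 7.2e-03, adjusted p = 0.531 with an estimated correlation). Among them, the heart and mesoderm regulator HAND1 differed by -3.90 and BMP4 by -3.34. The cardiac muscle list had 0 higher, 12 lower and 12 not called (camera adjusted p = 7.2e-03, adjusted p = 0.792 with an estimated correlation). Its call was lost at 0.0646 with median centring. MYL4, an atrial myosin light chain, differed by -3.60, and MYH6, the atrial heavy chain, by -2.29 over all arrays but by 0.04 within scan session 1, which held 1 EB array. The imprinted list had 1 higher, 10 lower and 12 not called (camera adjusted p = 1.9e-03, adjusted p = 0.437 with an estimated correlation). Among them, the growth inhibitor CDKN1C differed by -5.26 and the non-coding RNA H19 by -4.61.

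Of the remaining lists in hESC-EC against EB, none passed. The basement membrane list had 3 of 20 higher and 7 lower (camera adjusted p = 0.189), and EB replicate 4 lay apart in its mean (0.13 against 0.50). Among them, LAMA1, a laminin chain, differed by -5.08. The blood cell list had 3 of 27 higher and 9 lower (camera adjusted p = 0.338). Among them, the gamma-globin gene HBG1 differed by -4.06. The smooth muscle and pericyte list had 4 of 17 higher and 7 lower (camera adjusted p = 0.904). Among them, MYLK, the myosin light chain kinase, differed by 3.97. The HOX list had 4 of 30 higher and 6 lower (camera adjusted p = 0.342), and the immediate early and heat shock list 5 of 21 higher and 2 lower (camera adjusted p = 0.276). Cell cycle genes had 5 of 40 higher and 6 lower (camera adjusted p = 0.854), interferon response genes 2 of 32 higher and 6 lower (camera adjusted p = 0.677) and neuroectoderm and neuron genes 1 of 26 higher and 7 lower (camera adjusted p = 0.391). For venous and lymphatic genes the counts were 0 of 13 higher and 2 lower (camera adjusted p = 0.994). The mean and the direction of the test differed in sign for the endothelial activation, cell cycle, interferon response and HOX lists, and the mean and the median for the venous and lymphatic list. Some lists that had missed passed in other settings: angiogenic (1.3e-03), cell cycle (0.0203) and immediate early (0.0160) with median centring, angiogenic (0.0416) with the slide block, and angiogenic (0.0453) with the session block. In all, 1374 genes were higher and 3942 lower in hESC-EC, and adjusting over the list alone gave every list the same counts. The share of higher genes depended on the scaling: median centring called 4366 higher among 7477, and the scanner software's log ratios put the median difference of all genes at 0.17 in this comparison and at -0.14 in EB against hESC. Slide and session blocks called 5834 and 5474 genes, and fits within session 1, session 2 and slide 5 alone 5076, 5795 and 5826. Each of these 3 fits had 1 array in an arm, assumed to vary like the other groups. Only slides 4 and 5 held more than 1 group, so every value with the slide as a block rests on slide 5 (EB replicates 1 and 2, hESC-EC replicate 1 and hESC replicate 2) and slide 4 (EB replicate 4 and HUVEC replicates 2 to 4).

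**Figure D1:**
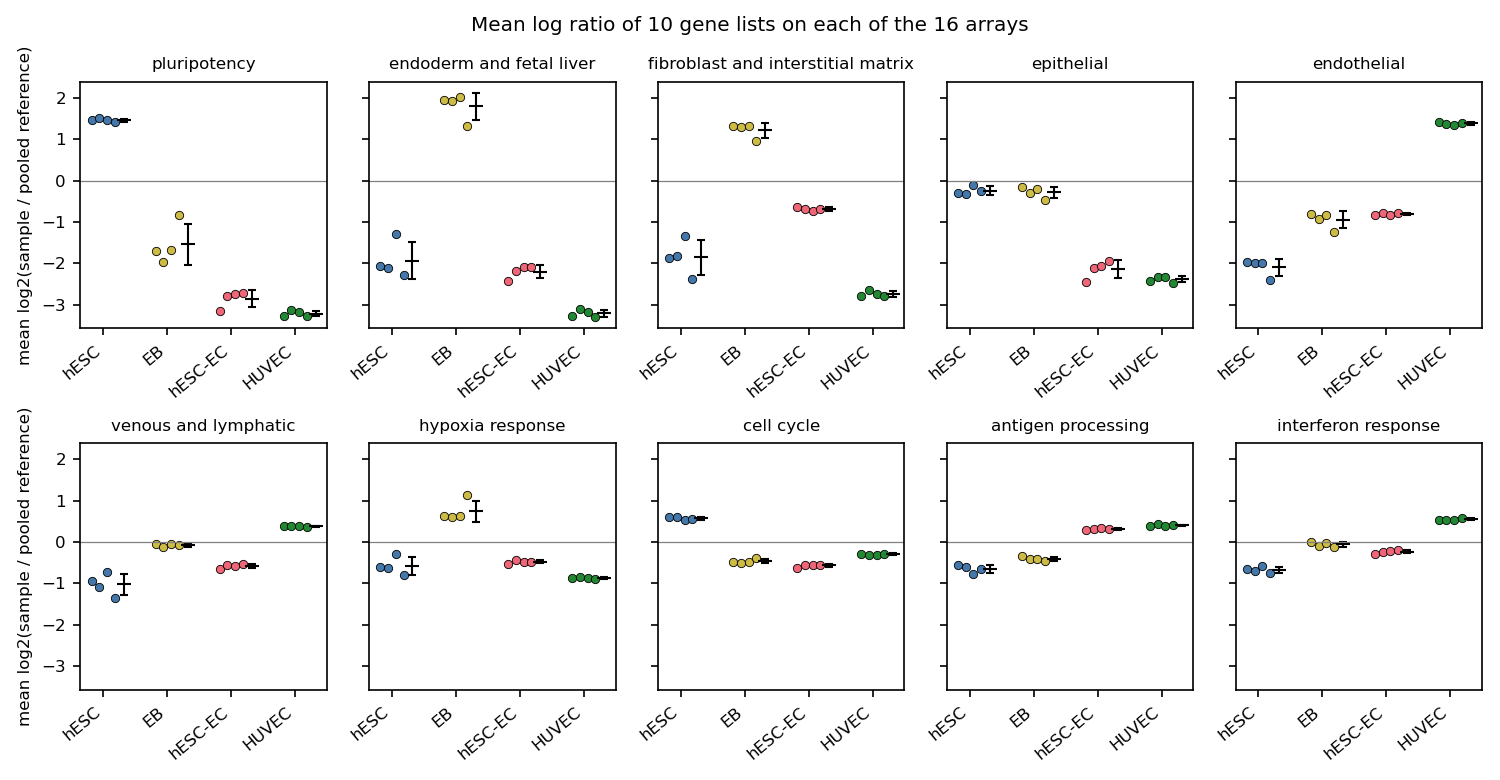
Mean log2 ratio to the reference over the measured genes of 10 gene lists (vertical axis), with 1 point per array in each of the 4 groups and the group mean with its SD bar beside the points. The endothelial list sits at -2.10 ± 0.21 in hESC, -0.95 ± 0.21 in EB, -0.81 ± 0.03 in hESC-EC and 1.38 ± 0.03 in HUVEC.

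The comparison of hESC-EC with HUVEC asked how far endothelial cells made from stem cells differed from endothelial cells of the umbilical vein. Most endothelial genes were lower in hESC-EC. VWF, which encodes the clotting protein von Willebrand factor (chromosome 12, 5928444 to 5928503), stood at -3.99 ± 0.12 against 2.58 ± 0.08, 95.4-fold lower (adjusted p = 2.1e-14). Both sort markers were lower too, PECAM1 at -0.75 ± 0.10 against 2.03 ± 0.05 (adjusted p = 2.3e-09) and CDH5 at -0.70 ± 0.16 against 1.92 ± 0.15 (adjusted p = 5.1e-11). Many matrix genes were higher. PDGFRB, a growth factor receptor of pericytes and fibroblasts, stood at 1.11 ± 0.11 against -4.68 ± 0.13 (55.4-fold, adjusted p = 1.1e-11). MLPH (chromosome 2, 238127263 to 238127322) had the largest positive difference, 132-fold.

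The endothelial list had 0 higher, 33 lower and 8 not called of 41 (camera adjusted p = 1.5e-20, adjusted p = 0.0710 with an estimated correlation). Its mean difference was -2.19 over all arrays, -2.59 with the slide as a block, -2.23 with the scan session as a block and -2.18 within session 1. hESC-EC and HUVEC shared no slide, so the slide block sets hESC-EC replicate 1 against EB replicates 1 and 2, and HUVEC against EB replicate 4 alone. That EB array was the lowest of its group in the endothelial list (-1.25 against -0.93 to -0.80). After VWF, the largest differences of the list were in MMRN1, a platelet and endothelial adhesive protein (-5.81), and ICAM2, an adhesion molecule (-5.77). The arterial and Notch list had 4 higher, 8 lower and 10 not called (camera adjusted p = 0.0421, adjusted p = 0.543 with an estimated correlation). Among them, the kinase gene BMX stood at -4.19 ± 0.30 against 2.64 ± 0.06, and CXCR4 and DEPP1 differed by -4.24 and -4.08. The venous and lymphatic list had 0 higher, 6 lower and 7 not called (camera adjusted p = 0.0187, adjusted p = 0.458 with an estimated correlation). Among them, the hyaluronan receptor LYVE1 differed by -3.35, the scavenger receptor STAB1 by -2.32 and the angiopoietin receptor TEK by -2.19. The interferon response list had 0 higher, 12 lower and 20 not called (camera adjusted p = 4.3e-05, adjusted p = 0.0710 with an estimated correlation). Among them, IFI27 differed by -5.21, IFI44L by -2.58 and MX1 by -2.31. The cell cycle list had 1 higher, 3 lower and 36 not called (camera adjusted p = 8.3e-03, adjusted p = 0.234 with an estimated correlation). Among them, the spindle gene DLGAP5 differed by -1.47. The call was lost at 0.235 with the slide as a block, and hESC-EC replicate 1, the only hESC-EC array that block uses, lay apart in the mean of the list (-0.62 against -0.54). The angiogenic factors and receptors split into 8 higher, 11 lower and 20 not called (camera adjusted p = 0.275). Among them TIMP3, a metalloproteinase inhibitor, was 23.8-fold higher and MMP1, the interstitial collagenase, 33.0-fold lower. The endothelial activation list had 3 higher, 4 lower and 14 not called (camera adjusted p = 0.513). In it the chemokine gene CCL2 stood at -5.64 ± 0.37 against 0.74 ± 0.05, and the cytokine gene IL1B, dim in HUVEC, was at least 4.23-fold higher (adjusted p = 7.4e-09).

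Between hESC-EC and HUVEC the fibroblast and interstitial matrix list had 17 higher, 1 lower and 8 not called (camera adjusted p = 2.4e-09, adjusted p = 0.240 with an estimated correlation). FBLN1, an extracellular matrix glycoprotein, stood at -0.28 ± 0.13 against -6.27 ± 0.12, and the collagen genes COL6A3 and COL3A1 differed by 5.28 and 4.25. The endoderm and fetal liver list had 14 higher, 1 lower and 15 not called (camera adjusted p = 1.5e-04, adjusted p = 0.543 with an estimated correlation). The call of the list was lost at 0.647 with the slide as a block and at 0.158 with all spots in the background fit. ALB, dim in HUVEC, was at least 7.43-fold higher, FOXA1 differed by 3.32 and the endoderm and heart regulator GATA6 by -3.01. The smooth muscle and pericyte list had 6 higher, 2 lower and 9 not called (camera adjusted p = 0.0445, adjusted p = 0.543 with an estimated correlation). It lost its call under both blocks, at 0.571 by slide and 0.0647 by session. It also lost it without hESC-EC replicate 2 (0.0577), without HUVEC replicate 4 (0.0556) and with all spots in the background fit (0.334). RGS5, a pericyte regulator of G-protein signalling, differed by -5.68 and MYLK by 3.15. The cardiac muscle list had 3 higher, 0 lower and 21 not called (camera adjusted p = 5.2e-03, adjusted p = 0.698 with an estimated correlation). Its direction turned with the slide as a block, at adjusted p = 0.512, where HUVEC is set against EB replicate 4, whose mean of the list was -2.54 against -2.10 to -1.76 on the other EB arrays. In the smooth muscle and endoderm lists that array was also the lowest EB array (-0.94 and 1.31). The cardiac list also lost its call at 0.443 with all spots in the background fit. Of its members NKX2-5, a heart transcription factor, differed by 2.11, and CSRP3 and MYBPC3 by 1.37 and 1.14, both below 0 with the slide as a block and MYBPC3 not called with all spots in the background fit, where it differed by 0.58. SPON2, a secreted matrix protein (87.6-fold), and the signalling ligand WNT5A (56.6-fold) were among the largest positive differences.

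HOX genes, which mark position along the body axis, went both ways between hESC-EC and HUVEC, 6 higher, 8 lower and 16 not called of 30, or 6 higher and 9 lower when adjusted over the list alone (camera adjusted p = 0.444, with mean and median of opposite sign). HOXC9 stood at 1.83 ± 0.08 against -3.05 ± 0.13 (adjusted p = 1.6e-11), HOXA13, dim in HUVEC, was at least 21.2-fold higher, and HOXA4 stood at -1.79 ± 0.12 against 1.78 ± 0.06 (adjusted p = 2.2e-11). The imprinted list had 5 higher, 4 lower and 14 not called (camera adjusted p = 0.513). Among them, the non-coding RNA MEG3 differed by -4.98, MEST by 3.40 and NNAT by -2.55. The basement membrane list had 7 of 20 higher and 3 lower (camera adjusted p = 0.120). Among them, the laminin chain LAMA4 differed by -4.36. The epithelial list had 8 of 25 higher and 2 lower (camera adjusted p = 0.0807). Among them, the keratin gene KRT8 differed by 2.40. The primitive streak and mesoderm list had 6 of 21 higher and 3 lower (camera adjusted p = 0.115). Among them, SNAI2, a driver of mesenchymal transition, differed by 5.14 and TCF15 by -4.42. None of the 30 pluripotency genes was called (camera adjusted p = 0.112). The counts were 5 of 26 higher and 3 lower for neuroectoderm and neuron (camera adjusted p = 0.382) and 5 of 24 higher and 1 lower for hypoxia response (camera adjusted p = 0.126). The immediate early and heat shock counts were 6 of 21 higher and 0 lower (camera adjusted p = 0.296). They were 1 of 27 higher and 1 lower for blood cell (camera adjusted p = 0.0643). The antigen processing counts were 2 of 18 higher and 2 lower (camera adjusted p = 0.939, with the mean below 0 and the test upward). Without 1 array, lists that had missed passed: pluripotency (0.0421), epithelial (0.0171) and blood cell (0.0421) without hESC-EC replicate 1, and blood cell (0.0455) without HUVEC replicate 2. Other processing let more lists pass: pluripotency (0.0384), epithelial (0.0219) and blood cell (9.8e-03) with Agilent's log ratios, primitive streak (0.0471) and blood cell (0.0150) with median centring, and pluripotency (7.1e-07), neuroectoderm (6.4e-04) and hypoxia response (6.4e-05) with the slide block. Further ones were pluripotency (0.0158) with the session block. The slide block values here use EB replicate 4, the highest EB array in pluripotency (-0.83 against -1.96 to -1.68), neuroectoderm (0.04 against -0.73 to -0.53) and hypoxia response (1.14 against 0.61 to 0.63), as the only link to HUVEC. In all, 1270 genes were higher and 1242 lower, and median centring called 1120 higher among 2896. Slide and session blocks called 2856 and 2549 genes, and fits within session 1 alone 2573, and session 2 held no HUVEC array.

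**Figure D2:**
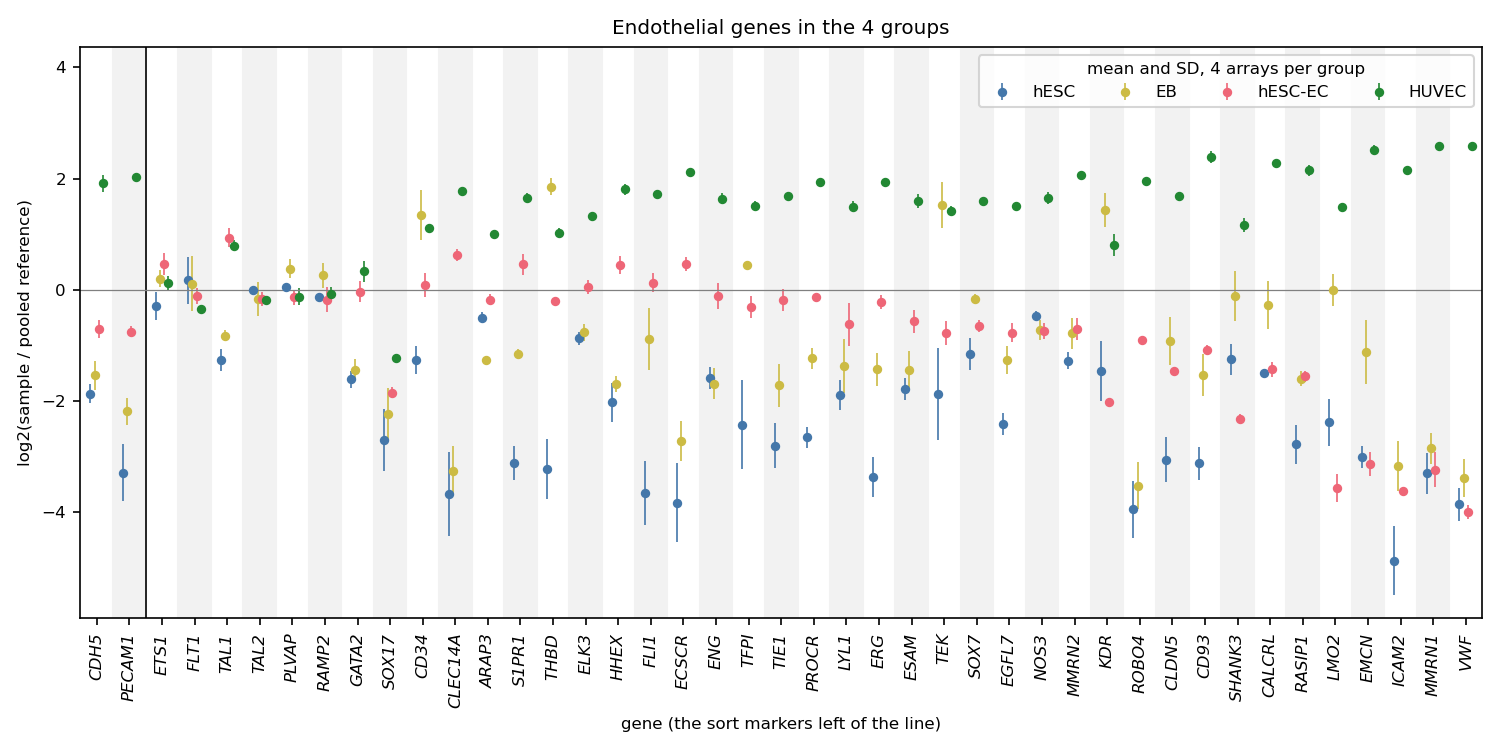
Mean log2 ratio to the reference with SD (vertical axis) of the sort markers PECAM1 and CDH5, left of the line, and the 41 measured endothelial genes in each of the 4 groups of 4 arrays. HUVEC lies above hESC-EC in the 33 genes called between them and in both sort markers.

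**Figure D3:**
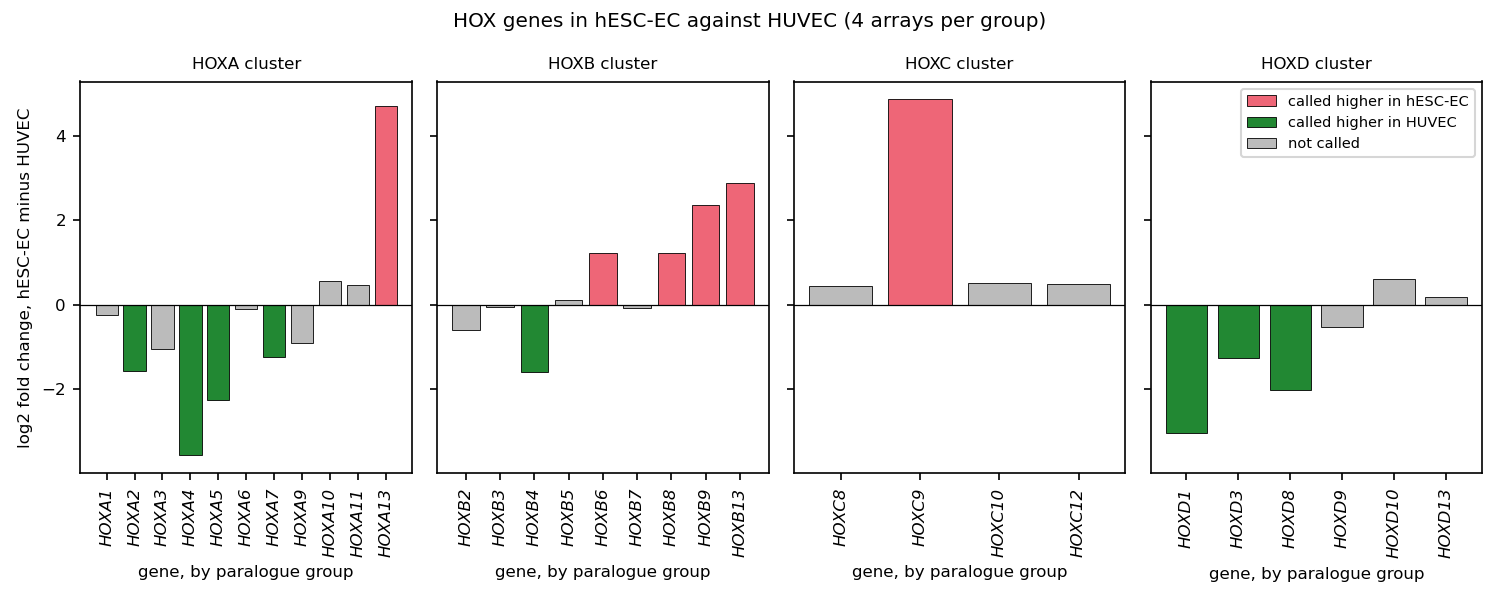
Log2 difference between hESC-EC and HUVEC (vertical axis, bars from 0) for the 30 measured HOX genes, arranged by cluster and paralogue number. Red bars are the 6 genes called higher in hESC-EC, green bars the 8 called higher in HUVEC, and grey bars the 16 not called.

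Across all genes, hESC-EC arrays resembled HUVEC arrays more than EB arrays. Pearson's r across genes averaged 0.591 between hESC-EC and HUVEC arrays (0.573 to 0.610) and -0.0677 between hESC-EC and EB arrays. The difference of 0.658 was the largest of the 70 assignments of the 8 HUVEC and EB arrays (exact permutation test, both sides, p = 0.0286, the smallest this design can give). Genes are not independent replicates, so r describes only the likeness of arrays in their ratios to the pooled reference. The pool held RNA of stem cells, embryoid bodies and heart, so r also depends on its make-up. HUVEC and EB arrays each resembled their own group closely (mean r 0.987 and 0.908). Nearly any consistent difference between them would therefore give this p. hESC arrays, not part of the test, had a mean r of -0.0295 with hESC-EC arrays. Within session 1 the difference in r between HUVEC and EB arrays was 0.629. The changes against EB were shared as well: 785 genes were higher and 2857 lower in both hESC-EC and HUVEC than in EB, and 106 were called in opposite directions. The balance of higher and lower depends on the scaling, since median centring called more genes higher than lower in both comparisons. The overlap was not recomputed with median centring. Independent calls would share 749 genes. Because both comparisons used the same EB arrays, unchanged groups were simulated around shared controls, and these gave an r of the log2 differences across genes of 0.501 against 0.789 observed, and a covariance of 0.00923 against 0.976. With the EB arrays divided between the comparisons, 3529 to 3594 genes were shared. Both checks address only the noise of shared EB arrays, and not expression particular to EB as the source of the sharing. Of the 2857 genes lower in both, 1275 were lower in hESC than in EB too. Another 1333 were lower in both endothelial groups than in hESC as well. Of the 785 higher in both, 101 were higher in hESC than in EB too, and 489 were higher than in hESC as well.

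The comparison of EB with hESC asked what differed between day 12 aggregates and undifferentiated cells. Line, series and RNA extraction cannot be separated from differentiation here. Nearly all pluripotency genes were called lower in EB, and more genes of liver, matrix, vessels and body axis were called higher than lower. POU5F1 (chromosome 6, 31240157 to 31240216), a core pluripotency factor whose transcript closely resembles those of its pseudogenes, stood at -2.76 ± 1.28 against 2.85 ± 0.32 (adjusted p = 7.3e-09). NANOG stood at -2.61 ± 1.27 against 2.72 ± 0.51 (adjusted p = 2.2e-08). AFP, the fetal plasma protein alpha-fetoprotein, stood at 3.88 ± 0.66 against -4.78 ± 0.95, 403-fold higher (adjusted p = 1.6e-11), and LUM at 3.92 ± 0.30 against -4.88 ± 1.91, 445-fold higher (adjusted p = 3.0e-09). PECAM1 was higher at -2.18 ± 0.24 against -3.29 ± 0.51 (adjusted p = 6.8e-05), a difference of 1.11. It missed the 2-fold minimum, and so its call, with the slide block (log2 difference 0.69), the session block (0.96), median centring (0.71) and without hESC replicate 4 (0.90), narrowly so at 0.96 and 0.90. CDH5 was not called (log2 difference 0.33).

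The pluripotency list in EB against hESC had 0 higher, 28 lower and 2 not called (camera adjusted p = 3.3e-14, adjusted p = 0.130 with an estimated correlation), led after POU5F1 and NANOG by LEFTY1, a Nodal antagonist (-5.26), the Nodal co-receptor CRIPTO (-4.98), SOX2 (-4.83) and L1TD1 (-4.65). The cell cycle list had 0 higher, 18 lower and 22 not called (camera adjusted p = 1.4e-14, holding at adjusted p = 7.2e-04 with an estimated correlation). Among them, the checkpoint kinase BUB1 differed by -2.38 and the replication helicase subunits MCM4 and MCM6 by -1.92 and -1.81. The endoderm and fetal liver list had 21 higher, 1 lower and 8 not called (camera adjusted p = 1.4e-09, adjusted p = 0.162 with an estimated correlation). Among them, AHSG differed by 8.67, TTR by 8.29 and the fibrinogen chains FGA and FGB by 7.88 and 7.79. The fibroblast and interstitial matrix list had 20 higher, 1 lower and 5 not called (camera adjusted p = 1.6e-09, adjusted p = 0.162 with an estimated correlation). Among them, DCN differed by 7.79 and COL3A1 by 7.65. The basement membrane list had 12 higher, 0 lower and 8 not called (camera adjusted p = 1.2e-08, adjusted p = 0.159 with an estimated correlation). Among them, NID2 differed by 5.11. The endothelial list had 20 higher, 0 lower and 21 not called (camera adjusted p = 1.0e-06, adjusted p = 0.192 with an estimated correlation). Among them, the thrombin receptor THBD differed by 5.08, TEK by 3.40 and KDR by 2.89. hESC replicate 4 lay apart from the others of its group in the endothelial mean (-2.41 against -1.99). The arterial and Notch list had 10 higher, 0 lower and 12 not called (camera adjusted p = 4.0e-04, adjusted p = 0.162 with an estimated correlation). Among them, the semaphorin and growth factor receptor NRP1 differed by 3.22. The HOX list had 13 higher, 0 lower and 17 not called (camera adjusted p = 1.5e-05, adjusted p = 0.162 with an estimated correlation). Among them, HOXB3 stood at 1.76 ± 0.44 against -4.20 ± 1.38, and HOXB2 differed by 4.77. The hypoxia response list had 14 higher, 1 lower and 9 not called (camera adjusted p = 9.8e-06, adjusted p = 0.192 with an estimated correlation). Among them, NDRG1 differed by 4.15 and SLC2A1 by 4.04.

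In the same comparison the imprinted list had 12 higher, 1 lower and 10 not called (camera adjusted p = 7.6e-04, adjusted p = 0.162 with an estimated correlation). Among them, CDKN1C differed by 4.55 and H19 by 4.54. Blood cell genes had 9 of 27 higher and 0 lower (camera adjusted p = 2.1e-03, adjusted p = 0.162 with an estimated correlation). Among them, the globin gene HBG1 differed by 4.19 and HBE1 by 2.90. Interferon response genes had 10 of 32 higher and 1 lower (camera adjusted p = 6.6e-03, adjusted p = 0.162 with an estimated correlation). Among them, IFIT1 differed by 4.60. Primitive streak and mesoderm genes had 11 of 21 higher and 3 lower (camera adjusted p = 6.6e-03, adjusted p = 0.247 with an estimated correlation). Among them, SNAI2 differed by 4.46 and the mesoderm factor FOXF1 by 3.97. The list's call was lost at 0.0922 with the slide as a block. Angiogenic factors and receptors had 17 of 39 higher and 5 lower (camera adjusted p = 0.0215, adjusted p = 0.508 with an estimated correlation). EPAS1, a hypoxia-inducible factor, differed by 5.05. This call was lost at 0.214 with the slide as a block, 0.0737 with median centring and 0.0718 without hESC replicate 4. That array lay apart from the others of its group in the mean of the list (-1.95 against -1.37). The counts were 5 of 13 higher and 0 lower for venous and lymphatic (camera adjusted p = 0.0708) and 5 of 21 higher and 0 lower for endothelial activation (camera adjusted p = 0.0777). The cardiac muscle counts were 6 of 24 higher and 1 lower (camera adjusted p = 0.0727). They were 2 of 26 higher and 6 lower for neuroectoderm and neuron (camera adjusted p = 0.112) and 6 of 17 higher and 0 lower for smooth muscle and pericyte (camera adjusted p = 0.248). The epithelial counts were 4 of 25 higher and 4 lower (camera adjusted p = 0.461). The last were 5 of 21 higher and 2 lower for immediate early and heat shock (camera adjusted p = 0.579). The antigen processing counts were 2 of 18 higher and 0 lower (camera adjusted p = 0.625). Leaving out 1 array let further lists pass: venous and lymphatic (0.0460) without EB replicate 2, venous and lymphatic (0.0281) and endothelial activation (0.0420) without hESC replicate 3, endothelial activation (0.0446), neuroectoderm and neuron (0.0201) and cardiac muscle (0.0160) without EB replicate 4, and cardiac muscle (0.0314) without hESC replicate 1. Lists that had missed also passed in other settings: venous (0.0386) and cardiac muscle (0.0254) with Agilent's log ratios, venous (0.0345) with median centring, and venous (0.0454) with the session block. Settings chosen after seeing the data added neuroectoderm (0.0110) and cardiac muscle (0.0115) leaving out EB replicate 4 and hESC replicate 2. In all, 2703 genes were higher and 1334 lower, every list had the same counts adjusted over the list alone, and median centring called 2125 higher among 4484. EB replicate 4 stood apart from the other EB arrays in its liver, matrix, basement membrane and hypoxia lists, and leaving it out together with hESC replicate 2, chosen after seeing the data, gave 4444 calls here and 5507 in hESC-EC against EB. Slide and session blocks called 4799 and 3917 genes, and fits within session 1, session 2 and slide 5 alone 3309, 4717 and 4807. Here too each fit within a session or slide had an arm of 1 array, and its spread comes from other groups.

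Between hESC-EC and hESC, more pluripotency and epithelial genes were called lower than higher in hESC-EC, and more endothelial, angiogenic and HOX genes higher than lower. SOX2 (chromosome 3, 182914571 to 182914630) stood at -6.46 ± 0.50 against 2.13 ± 0.22, 383-fold lower (adjusted p = 4.2e-11), NANOG was 249-fold and POU5F1 202-fold lower. G0S2, an inhibitor of fat breakdown, was 95.6-fold higher, and the flow-responsive transcription factor KLF2 53.8-fold, and PTX3 differed by log2 6.57. PECAM1 was higher by 2.54 (adjusted p = 3.0e-09) and CDH5 by 1.16 (adjusted p = 5.5e-07). The pluripotency list had 0 higher, 26 lower and 4 not called (camera adjusted p = 8.0e-12, adjusted p = 0.134 with an estimated correlation). The epithelial list had 1 higher, 16 lower and 8 not called (camera adjusted p = 2.4e-06, adjusted p = 0.217 with an estimated correlation). Among them, EPCAM differed by -6.59 and MAL2 by -6.46. Cell cycle genes had 0 higher, 20 lower and 20 not called (camera adjusted p = 6.0e-08, holding at adjusted p = 0.0126 with an estimated correlation). Among them, ASPM differed by -2.86 and CENPF by -2.83. The endothelial list had 23 higher, 2 lower and 16 not called (camera adjusted p = 1.2e-06, adjusted p = 0.272 with an estimated correlation). Among them, CLEC14A differed by 4.30, ECSCR by 4.29 and the ETS factor FLI1 by 3.78. Angiogenic factors and receptors had 20 higher, 3 lower and 16 not called (camera adjusted p = 1.5e-05, adjusted p = 0.272 with an estimated correlation). Among them, EPAS1 differed by 5.30 and the endothelin receptor EDNRB by -4.13. The HOX list had 14 higher, 1 lower and 15 not called (camera adjusted p = 6.3e-06, adjusted p = 0.134 with an estimated correlation). Among them, HOXC9 differed by 4.82 and HOXA9 by 4.17.

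Antigen processing genes in hESC-EC against hESC had 5 of 18 higher and 0 lower (camera adjusted p = 1.1e-04, holding at adjusted p = 0.0426 with an estimated correlation). B2M, the light chain of class I molecules, differed by 3.24. Basement membrane genes had 8 of 20 higher and 1 lower (camera adjusted p = 1.1e-03, adjusted p = 0.350 with an estimated correlation). Among them, LAMB3 differed by 5.22. Fibroblast and interstitial matrix genes had 13 of 26 higher and 2 lower (camera adjusted p = 1.2e-03, adjusted p = 0.481 with an estimated correlation). Among them, the fibrillin gene FBN1 differed by 4.33. Interferon response genes had 5 of 32 higher and 1 lower (camera adjusted p = 1.8e-03, adjusted p = 0.134 with an estimated correlation), and endothelial activation genes 5 of 21 higher and 2 lower (camera adjusted p = 5.3e-03, adjusted p = 0.424 with an estimated correlation). In the activation list, the chemokine gene CXCL1 differed by 4.86. Neuroectoderm and neuron genes had 1 of 26 higher and 11 lower (camera adjusted p = 0.0473, adjusted p = 0.625 with an estimated correlation). Among them, CRABP1 differed by -2.54 over 3 hESC-EC arrays. That call was lost at 0.105 with the slide as a block, 0.0587 with the mean of all probes and 0.0927 with all spots in the background fit. It was also lost at 0.0517, 0.0642 and 0.0865 without hESC-EC replicate 1, hESC-EC replicate 3 and hESC replicate 3. The counts were 5 of 22 higher and 4 lower for arterial and Notch (camera adjusted p = 0.449), 4 of 13 higher and 1 lower for venous and lymphatic (camera adjusted p = 0.203) and 5 of 17 higher and 2 lower for smooth muscle and pericyte (camera adjusted p = 0.417). The cardiac muscle counts were 0 of 24 higher and 4 lower (camera adjusted p = 0.216). They were 6 of 21 higher and 5 lower for primitive streak and mesoderm (camera adjusted p = 0.690) and 2 of 30 higher and 5 lower for endoderm and fetal liver (camera adjusted p = 0.776). The blood cell counts were 5 of 27 higher and 3 lower (camera adjusted p = 0.248). The last were 6 of 24 higher and 5 lower for hypoxia response (camera adjusted p = 0.634) and 6 of 21 higher and 1 lower for immediate early and heat shock (camera adjusted p = 0.330). The imprinted counts were 5 of 23 higher and 6 lower (camera adjusted p = 0.792). The medians of the streak, smooth muscle and hypoxia lists were below 0 while their means and tests pointed up. Further lists passed without 1 array: cardiac muscle (0.0402) without hESC replicate 4, and immediate early and heat shock (0.0276) without hESC replicate 2. More lists passed in other settings: immediate early (0.0206) with median centring, and cardiac muscle (9.4e-03) with the slide block. Settings chosen after seeing the data added immediate early (0.0240) leaving out EB replicate 4 and hESC replicate 2. Apart from the others of their group were hESC replicate 4 in the endothelial and angiogenic means (-2.41 against -1.99 and -1.95 against -1.37) and hESC-EC replicate 1 in the pluripotency (-3.16 against -2.75), arterial (-1.14 against -0.98) and cell cycle means (-0.62 against -0.54). In all, 2239 genes were higher and 3435 lower, every list had the same counts adjusted over the list alone, and median centring called 3459 higher among 6424. Slide and session blocks called 5857 and 5680 genes, and fits within session 1, session 2 and slide 5 alone 5733, 5854 and 5844. The last 2 of these set the same 1 array against 1, with the spread taken from other groups, and so add little.

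HUVEC against EB gave the reference difference for endothelial cells of a vessel. VWF was 62.4-fold higher in HUVEC (2.58 ± 0.08 against -3.38 ± 0.35, adjusted p = 1.2e-14), EFEMP1, a matrix glycoprotein, 123-fold, BMX 107-fold and MMP1 96.5-fold. AHSG was lower at -7.14 ± 0.22 against 3.96 ± 0.69 and LUM at -7.14 ± 0.20 against 3.92 ± 0.30. PECAM1 and CDH5 were higher by log2 4.21 and 3.45. The endothelial list had 32 higher, 0 lower and 9 not called (camera adjusted p = 7.1e-13, adjusted p = 0.188 with an estimated correlation). Among them, the guidance receptor ROBO4 differed by 5.47. Interferon response genes had 13 higher, 4 lower and 15 not called (camera adjusted p = 1.6e-03, adjusted p = 0.188 with an estimated correlation). Among them, IFI27 differed by 4.17 and IFIT1 by -3.70. Antigen processing genes had 6 higher, 0 lower and 12 not called (camera adjusted p = 1.6e-03, adjusted p = 0.188 with an estimated correlation). Among them, TAP1 differed by 2.16. The endoderm and fetal liver list had 0 of 30 higher and 23 lower (camera adjusted p = 3.2e-10, adjusted p = 0.278 with an estimated correlation) and fibroblast and interstitial matrix 1 of 26 higher and 20 lower (camera adjusted p = 6.7e-07, adjusted p = 0.311 with an estimated correlation). For epithelial the counts were 2 of 25 higher and 20 lower (camera adjusted p = 6.7e-07, adjusted p = 0.266 with an estimated correlation). Cardiac muscle had 0 of 24 higher and 16 lower (camera adjusted p = 1.2e-05, adjusted p = 0.370 with an estimated correlation), hypoxia response 0 of 24 higher and 13 lower (camera adjusted p = 9.4e-05, adjusted p = 0.353 with an estimated correlation) and pluripotency 1 of 30 higher and 18 lower (camera adjusted p = 1.6e-03, adjusted p = 0.370 with an estimated correlation). For primitive streak and mesoderm the counts were 2 of 21 higher and 12 lower (camera adjusted p = 8.2e-03, adjusted p = 0.353 with an estimated correlation). The streak list lost its call at 0.0511 with all spots in the background fit. Basement membrane had 3 of 20 higher and 12 lower (camera adjusted p = 0.0315, adjusted p = 0.448 with an estimated correlation), lost at 0.112 and 0.0689 with the slide and the session as a block and at 0.432 with median centring. EB replicate 4 lay apart from the other EB arrays in the means of the endoderm, fibroblast, basement membrane and hypoxia lists. No other list passed: arterial and Notch had 6 of 22 higher and 7 lower, venous and lymphatic 6 of 13 higher and 2 lower, angiogenic 17 of 39 higher and 10 lower, activation 7 of 21 higher and 4 lower, neuroectoderm 3 of 26 higher and 11 lower, smooth muscle 2 of 17 higher and 8 lower, blood cell 2 of 27 higher and 11 lower, cell cycle 3 of 40 higher and 2 lower, immediate early 5 of 21 higher and 6 lower, imprinted 4 of 23 higher and 11 lower and HOX 7 of 30 higher and 9 lower (7 higher and 10 lower adjusted over the list alone). The mean and the test differed in sign for the arterial, immediate early and HOX lists. Without single arrays further lists passed: venous and lymphatic (0.0482), angiogenic factors and receptors (0.0482) and imprinted (0.0482) without EB replicate 2, venous and lymphatic (0.0499), angiogenic factors and receptors (0.0469) and imprinted (0.0469) without HUVEC replicate 1, venous and lymphatic (0.0477), angiogenic factors and receptors (0.0448), blood cell (0.0490) and imprinted (0.0448) without HUVEC replicate 2, angiogenic factors and receptors (0.0473) without EB replicate 1, and angiogenic factors and receptors (0.0495), blood cell (0.0433), cell cycle (0.0433) and imprinted (0.0444) without EB replicate 4. Lists also passed in other settings: blood cell (0.0341) and imprinted (0.0313) with Agilent's log ratios, angiogenic (4.3e-03), neuroectoderm (0.0452), blood cell (2.9e-03) and cell cycle (3.7e-05) with median centring, and angiogenic (0.0327), endothelial activation (0.0481), neuroectoderm (0.0228) and blood cell (0.0304) with the slide block. Further ones were venous (0.0366), angiogenic (0.0369), blood cell (0.0364) and imprinted (0.0366) with no filter on dim probes, venous (0.0329), angiogenic (0.0304), blood cell (0.0329), cell cycle (0.0363) and imprinted (0.0337) with the mean of all probes, and imprinted (0.0492) with the replicate block. Settings chosen after seeing the data added venous (0.0382), angiogenic (0.0205), endothelial activation (0.0340), cell cycle (0.0382) and imprinted (0.0340) with all spots in the background fit, and angiogenic (0.0410), blood cell (0.0413), cell cycle (0.0410) and imprinted (0.0413) leaving out EB replicate 4 and hESC replicate 2. In all, 1804 genes were higher and 4112 lower, and median centring called 5517 higher among 8582. Slide and session blocks called 5688 and 6138 genes, and fits within session 1 and slide 4 alone 5779 and 5713. Both had EB replicate 4 as the only EB array, assumed to vary like the others.

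HUVEC against hESC gave the same reference difference from undifferentiated cells. MMP1 was 436-fold higher in HUVEC (3.28 ± 0.09 against -5.49 ± 0.71, adjusted p = 1.7e-14), EFEMP1 331-fold and ICAM2 131-fold. SOX2 was lower at -6.85 ± 0.17 against 2.13 ± 0.22, and NANOG and EPCAM differed by -8.66 and -8.39. PECAM1 and CDH5 were higher by log2 5.31 and 3.78. The endothelial list had 36 higher, 0 lower and 5 not called (camera adjusted p = 1.0e-20, holding at adjusted p = 0.0347 with an estimated correlation), interferon response 19 of 32 higher and 2 lower (camera adjusted p = 2.5e-09, holding at adjusted p = 0.0115 with an estimated correlation) and antigen processing 7 of 18 higher and 0 lower (camera adjusted p = 2.8e-05, holding at adjusted p = 0.0175 with an estimated correlation). For cell cycle the counts were 0 of 40 higher and 18 lower (camera adjusted p = 2.8e-06, holding at adjusted p = 0.0175 with an estimated correlation, but lost at 0.101 with median centring). Pluripotency had 0 of 30 higher and 28 lower (camera adjusted p = 3.0e-12, adjusted p = 0.0784 with an estimated correlation), epithelial 2 of 25 higher and 18 lower (camera adjusted p = 7.8e-07, adjusted p = 0.159 with an estimated correlation) and HOX 14 of 30 higher and 0 lower (camera adjusted p = 7.9e-06, adjusted p = 0.121 with an estimated correlation). For angiogenic factors and receptors the counts were 22 of 39 higher and 8 lower (camera adjusted p = 1.1e-04, adjusted p = 0.312 with an estimated correlation). hESC replicate 4 lay apart from the others of its group in the endothelial and angiogenic means (-2.41 against -1.99 and -1.95 against -1.37). Venous and lymphatic had 7 of 13 higher and 1 lower (camera adjusted p = 4.0e-03, adjusted p = 0.203 with an estimated correlation). Among them, the venous regulator NR2F2 differed by 4.91. Arterial and Notch had 7 of 22 higher and 4 lower (camera adjusted p = 0.0260, adjusted p = 0.443 with an estimated correlation). For endothelial activation the counts were 6 of 21 higher and 1 lower (camera adjusted p = 3.3e-03, adjusted p = 0.383 with an estimated correlation). Endoderm and fetal liver had 0 of 30 higher and 18 lower (camera adjusted p = 2.0e-03, adjusted p = 0.554 with an estimated correlation). Cardiac muscle had 0 of 24 higher and 10 lower (camera adjusted p = 9.1e-04, adjusted p = 0.554 with an estimated correlation). Both calls were lost with the slide as a block, at 0.505 and 0.116, and with all spots in the background fit, at 0.160 and 0.0806. Neuroectoderm and neuron had 2 of 26 higher and 13 lower (camera adjusted p = 0.0365, adjusted p = 0.607 with an estimated correlation). It was lost at 0.141 with all spots in the background fit and at 0.0522 without hESC replicate 3. No other list passed: primitive streak had 4 of 21 higher and 7 lower, smooth muscle 3 of 17 higher and 5 lower, fibroblast 7 of 26 higher and 13 lower, blood cell 3 of 27 higher and 3 lower, hypoxia 4 of 24 higher and 7 lower, immediate early 6 of 21 higher and 5 lower, imprinted 7 of 23 higher and 8 lower and basement membrane 8 of 20 higher and 3 lower (8 higher and 4 lower adjusted over the list alone). The median and the test differed in sign for the immediate early list. A further list passed without 1 array: fibroblast and interstitial matrix (0.0424) without hESC replicate 4. Other settings let further lists pass: basement membrane (0.0176) with median centring, and basement membrane (0.0112) and hypoxia response (0.0251) with the slide block. Settings chosen after seeing the data added basement membrane (0.0257) with all spots in the background fit. In all, 2366 genes were higher and 3511 lower, and median centring called 4075 higher among 6821. Slide and session blocks called 6105 and 6012 genes, and fits within session 1 alone 6059.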

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

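The tests of the lower endothelial genes in hESC-EC and the hypoxia test of EB replicate 4 were chosen only after the results were seen.

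Differences from EB were not alike in hESC-EC and HUVEC for 9 lists, by a test of the difference itself, which is the comparison of hESC-EC with HUVEC. The camera adjusted p was 1.5e-20 for endothelial (mean -2.19), 2.4e-09 for fibroblast and interstitial matrix, 4.3e-05 for interferon response, 1.5e-04 for endoderm and fetal liver, 5.2e-03 for cardiac muscle, 8.3e-03 for cell cycle, 0.0187 for venous and lymphatic, 0.0421 for arterial and Notch and 0.0445 for smooth muscle and pericyte. None of these passed with an estimated correlation, where the endothelial and interferon lists came nearest at 0.0710. With the slide as a block, 4 of the 9 lost their call: endoderm and fetal liver (0.647), smooth muscle and pericyte (0.571), cell cycle (0.235) and cardiac muscle (0.512, direction turned). Smooth muscle and pericyte also lost it with the session as a block (0.0647). The 2 groups share no slide, so the slide block rests on hESC-EC replicate 1 and, for HUVEC, on EB replicate 4, the lowest EB array in the endoderm (1.31), smooth muscle (-0.94) and cardiac lists (-2.54) and the highest in cell cycle (-0.38).

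The endothelial list was lower in hESC-EC than in HUVEC, 33 of 41 genes. A difference between slides or scan sessions is argued against: taking each endothelial group against EB arrays of its own slide left a mean difference of -2.59 (SD between arrays up to 0.21). That value rests on 1 hESC-EC array and, on the HUVEC side, on EB replicate 4, the lowest EB array in this list (-1.25 against -0.93 to -0.80). Within session 1, with 3 hESC-EC and 4 HUVEC arrays, the difference was -2.18, and the SD of the list mean within hESC-EC and within HUVEC, each spread over 2 slides, was 0.03. Carry-over of embryoid body cells in their original mix is argued against as well. The 30 measured endoderm and fetal liver genes held a median share of 0.0471 of their EB level (quartiles 0.0135 and 0.408), where the lower endothelial genes would need 0.75. These genes do not test carry-over of other embryoid body cells, such as those that make matrix. The fibroblast and interstitial matrix list had a median difference of -1.88 between hESC-EC and EB. Dilution by cells without endothelial transcripts would lower all the genes alike. Over 26 genes at least 8-fold higher in HUVEC than in hESC, the differences lay between -6.58 and -1.16. Their interquartile range was 1.87 (0.224 from measurement error alone), so dilution by such cells is not the whole cause. The genes were chosen by their level in hESC. The test therefore does not cover diluting cells of another kind that express some of them. Fibroblast-like cells grown beside the sorted cells remain open, because the median of the fibroblast and interstitial matrix list was 1.58 higher but endothelial cells in culture can express such genes, and the sort on CD31 and CD144 before culture would have removed them only at that time. A biological difference between endothelial cells made from stem cells and those of a vessel, which the design names, also stays open and was not tested. The hESC-EC came from the H9 line and HUVEC from another source, so genotype and any difference in culture cannot be separated from origin.

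Single arrays stood far from the other 3 of their group (Dixon's ratio of gap to range above its 95% critical value) in 9 of 88 list means, where chance alone gives about 1 in 20. On EB replicate 4 these were endoderm and fetal liver (0.863), fibroblast and interstitial matrix (0.911), basement membrane (0.927) and hypoxia response (0.959). On hESC-EC replicate 1 they were arterial and Notch (0.852), pluripotency (0.856) and cell cycle (0.964), and on hESC replicate 4 endothelial (0.927) and angiogenic factors and receptors (0.897). Among named genes the ratio passed that value in 64 of 731 cases: 32 in EB, of which 31 were on replicate 4, 12 in hESC-EC, of which 10 were on replicate 1, 10 in HUVEC and 10 in hESC. The sort markers passed it in 0 of 8.

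EB replicate 4 was the 1 EB array of scan session 1, and its mean r with the other EB arrays was 0.858. Across all genes the session is a candidate source. The difference between sessions within EB correlated with that within hESC-EC (0.368) and hESC (0.309), each resting on 1 array scanned apart. The lists that set replicate 4 apart did not all move with it. In endoderm and fetal liver, hESC-EC replicate 1 (session 2) stood at -2.44 against -2.19 to -2.08, opposite to EB. In hypoxia response (-0.52 against -0.49 to -0.44) and fibroblast (-0.64 against -0.75 to -0.69) it went as in EB but by less. In these lists and basement membrane, hESC replicate 2 lay within its group's range. The r thus does not show that the session moved them. Undifferentiated cells left in the embryoid bodies are argued against for the hypoxia response list, which stood 0.517 above the other EB arrays, themselves above hESC. For pluripotency genes they cannot be told apart from other differences: over 243 genes at least 4-fold higher in hESC than on the other EB arrays, 91.4% were higher on replicate 4, with a fitted hESC share of 0.0899 (bootstrap 95% interval 0.0774 to 0.104). The bootstrap resampled genes of this 1 array, so the interval does not cover differences between arrays. The same fit of each other EB array against the rest, replicate 4 among them, gave a share of 6.6e-05, with 5.49% to 41.8% of genes higher. A batch of embryoid bodies that differentiated less far would look like one with undifferentiated cells left and was not tested.

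In all 6 comparisons, fitted on their 8 arrays alone, only 1 of the 35 splits into 4 and 4, the real one, gave as many genes. That is the smallest share that 35 splits allow, so it cannot exclude chance. Every other split mixes the 2 groups, so differences between the groups widen its spread and lower its count. The splits therefore do not show how many of the single calls are true. The real counts were 5312 in hESC-EC against EB, 2530 in hESC-EC against HUVEC, 4021 in EB against hESC, 5641 in hESC-EC against hESC, 5920 in HUVEC against EB and 5865 in HUVEC against hESC. The highest of the other splits gave 1 gene in EB against hESC and 0 in the others.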

How the results depend on the processing

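The gene counts of the 6 comparisons stayed within 1.5 times their value in 150 of 168 alternatives, and leaving out each array in turn gave 5167 to 5503 in hESC-EC against EB, 2447 to 2566 in hESC-EC against HUVEC, 3868 to 4377 in EB against hESC, 5577 to 5830 in hESC-EC against hESC, 5780 to 6094 in HUVEC against EB and 5790 to 6058 in HUVEC against hESC. In the same order, Agilent's log ratios called 9350, 5824, 7035, 8988, 9957 and 9600 genes, the series values 9404, 5844, 7060, 8984, 9981 and 9616, and no minimum fold 16632, 11618, 14485, 15466, 16130 and 15443. The last setting drops the fold threshold, and for the others the cause was not tested. A total within 1.5 times does not mean that the same genes were called. In hESC-EC against EB, median centring kept 4192 of the 5316 main calls, and trend and robust settings kept 5314. In hESC-EC against HUVEC, the slide block kept 1964 of 2512, and trend and robust settings kept 2508. The overlap of the differences from EB rose from 3642 to 6130 with Agilent's log ratios and to 11831 with no minimum fold. The likeness of hESC-EC to HUVEC over EB kept its p under each alternative that left enough arrays, and within scan session 1 it was 0.629 with an exact permutation p = 0.2, the smallest that 5 assignments allow.

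The endothelial list in hESC-EC against EB passed only with median centring, at adjusted p = 0.0355, and its cause was not tested. With an estimated correlation, the endothelial list in hESC-EC against HUVEC gave 0.0710 and the pluripotency list in hESC-EC against hESC 0.134. With the slide as a block, the cardiac muscle list in hESC-EC against HUVEC changed direction at adjusted p = 0.512, as did its members CSRP3 (-0.067) and MYBPC3 (-0.47). The groups share no slide, so that value rests on hESC-EC replicate 1 and on EB replicate 4, whose cardiac mean was -2.54 against -2.10 to -1.76 on the other EB arrays, and the cause was not tested further. Over 2354 settings of 132 list results, 2172 kept direction and side of the threshold, 95 lost a call, 63 of them with an estimated correlation, 86 gained one and 1 turned. Over 5739 settings of 362 named gene results, 5715 kept it, 20 lost a call, 2 gained one and 2 turned. The pooled list total hides the effect of the correlation. With an estimated one, no list passed in hESC-EC against EB, hESC-EC against HUVEC or HUVEC against EB. Cell cycle passed in all comparisons with hESC, and antigen processing in hESC-EC and HUVEC against hESC. Endothelial and interferon response passed in HUVEC against hESC, and no other list passed. The preset of 0.01 lay below every list's estimate (0.0308 to 0.549). Quantile normalization of the intensities changes no log ratio and so tests nothing here.

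The replicate numbers showed no clear pairing of the samples. The residuals of arrays with the same number correlated at -0.196 to 0.259 over 24 pairs. By the mean correlation with arrays of the other groups, 6 of 16 arrays matched best with their own number. A weak pairing cannot be excluded, because the arrays scanned apart from their group carry different numbers. As a block, the replicate numbers gave 5320, 2515, 4038, 5675, 5919 and 5877 genes and an overlap of 3645. That block moved 1 list past its threshold (imprinted in HUVEC against EB, 0.0492). Using all spots in the background fit, chosen after seeing the data, gave 2050, 5196 and 5149 genes in the comparisons with HUVEC. Leaving out EB replicate 4 and hESC replicate 2, also chosen after seeing the data, gave 4444 to 6094 genes in the 5 comparisons with EB or hESC. Signal over background limits the values of dim genes, since on 1 array only 66.9% of spots were well above it in Cy5.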

Other observations

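The counts and genes below were chosen after their values were seen, and so was the division of the HOX genes. The balance of higher and lower genes depends on the scaling of the arrays, and these counts were not recomputed with median centring.

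hESC-EC differed from all 3 other groups in 225 genes that were higher and 297 that were lower. The same counts were 586 and 583 in HUVEC, 1275 and 101 in EB, and 766 and 589 in hESC. Among those highest in hESC-EC were MLPH (2.03 ± 0.21), the prostaglandin receptor PTGER2 (2.16 ± 0.10), the hair keratin KRT34 (2.12 ± 0.07), HSD11B1, which regenerates cortisol (1.93 ± 0.07), the BMP antagonist GREM1 (2.18 ± 0.05), PAPPA, a protease that frees insulin-like growth factor (2.38 ± 0.23), MYLK (1.70 ± 0.15) and the ion channel TRPA1 (1.58 ± 0.06). In each other group these 8 genes had means below -0.65. PTGER2, KRT34, GREM1 and TRPA1 were well above background on 0 HUVEC arrays, and KRT34 and TRPA1 on 1 EB array, so those means lie near the floor. Among those lowest were the RNA-binding protein CELF2 (-4.47 ± 0.14), the chemokine receptors CXCR4 (-5.99 ± 0.53) and ACKR3 (-5.84 ± 0.18), the corepressor RUNX1T1 (-3.24 ± 0.80) and PRICKLE1, a planar polarity protein (-2.45 ± 0.37). The others were DNAJC15 (-4.56 ± 0.12), the junction protein CGNL1 (-3.57 ± 0.16) and CYYR1 (-3.01 ± 0.16). CYYR1 was well above background on 1 hESC-EC array.

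Both endothelial groups were higher than both EB and hESC in 489 genes and lower in 1333. Of the 41 endothelial genes, 12 were higher in both endothelial groups, against 32 that were higher in HUVEC than in EB and hESC. The 12 were the receptors TIE1, ENG, ROBO4, S1PR1 and PROCR, the membrane proteins ECSCR and CLEC14A, and the transcription factors ERG, FLI1, TAL1, GATA2 and HHEX. Counted against hESC alone, 21 genes of the list were higher in hESC-EC but lower than in HUVEC, and 18 were not higher in hESC-EC than in hESC.

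Among HOX genes of paralogue groups 1 to 8, 2 of 18 were higher and 8 lower in hESC-EC than in HUVEC. Among those of groups 9 to 13, 4 of 12 were higher and 0 lower. The 4 were HOXA13, dim in HUVEC and at least 21.2-fold higher, and HOXB9, HOXB13 and HOXC9, with log2 differences of 2.37, 2.88 and 4.88. The division was not tested, because it follows the values.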
